A study of Caenorhabditis elegans with 2 samples.

How the data were processed

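ChIP-seq was done with an antibody against GFP on sonicated chromatin of whole young adult worms in 2 libraries given by the labels as biological replicates 1 and 2. The 2 libraries form 1 group, no control library was analysed here, and no comparison between conditions was possible. The aligner and the peak caller are not given in the sources used here, and neither is the read depth. The assembly is ce11, per the labels, which is the WBcel235 sequence used here for bases and annotation.

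The authors deposited ranked peak lists and lists thresholded by the irreproducible discovery rate (IDR), a measure of how far a peak's rank is shared between 2 lists. There is a ranked and a thresholded list for each replicate alone, a conservative pair from the comparison of the replicates, and an optimal pair from the pooled libraries. Each peak has a signal value given by the authors, whose scale is not given in the sources used here, so it was used only to rank, filter and describe peaks within a list. The ranked lists hold the −log10 of the global IDR of each peak as the authors wrote it. The score deposited with each peak is that IDR on a scaled form, which was recomputed and was equal in 99.99% of ranked peaks. The lowest deposited score in the conservative list, 830, corresponds to a global IDR of 0.01, so the planned stricter threshold of 0.01 removed no peak of that list. Of 1131 ranked peaks at or above that score, 45 are absent from the conservative list. Nothing in the sources used here says why, and the report leaves them out of the main set.

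The main set was the conservative list, 1086 peaks with a median width of 300 bp and no duplicate rows, each represented by its summit. Gene classes and starts came from Ensembl release 115. Of 2778 genes without a symbol there, 2773 were named through the RefSeq annotation by WormBase identifier, which also gave the amino acid of each tRNA gene. A start window ran from 500 bp upstream to 200 bp downstream of any annotated transcript start, and a gene was called bound if a summit lay in 1 of its windows. Random expectations came from 10000 placements of the summits on their own chromosomes, or, for the classes in the location plot, from 200000 random positions. Differences of medians, correlations and GC content were tested with 100000 permutations (10000 for the correlation over all ranked peaks). Gene lists with at least 5 members, 35 in all and written before the data were examined, were tested by two-sided Fisher exact tests with Benjamini-Hochberg adjustment. Protein-coding lists were compared with 19973 protein-coding genes and RNA lists with 46890 genes. Of 218 symbols in the lists made by hand, 215 were found. For words of 8 bases, both strands were merged and the 2 flank windows together held as many word positions as the summit window. Intervals are 95% Wilson intervals unless named as exact, a count of 0 was taken to allow up to 3 counts, and the threshold was 0.05. With only 2 replicates no outlier test was made.

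Named genes followed a rule written before the data were examined. It took ztf-28, the gene of each of the 25 peaks with the highest pooled signal (the gene whose window holds the summit, or else the nearest start), and up to 4 bound members with the highest signal from each list past the threshold and each tissue marker list.

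The tests were run on simulated summits first, in 100 sets of 1000 random positions and 20 sets with planted signal. The planted promoter share (400 summits in protein-coding windows), the planted tRNA list (150 summits, among 46890 genes) and the planted word (100 summits) were recovered in 20 of 20 sets each. In the 100 random sets, the promoter share passed the threshold in 7, the chosen word in 6, GC content in 5 and the signal difference in 5. The correlation was run on pairs of random values, not on summits, and passed in 3. Those values were not selected for agreement of ranks, so this does not bear on the correlation over passing peaks. At least 1 of the 35 lists was called in 20 of these 100 sets, at most 1 per set. The shift of all summits along each chromosome keeps the spacing of the peaks and was run as an alternative.

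Alternatives planned before the data were examined were the optimal list, a stricter IDR, merged overlapping peaks, each replicate's own list, start windows of 1000 and 200 bp or 250 and 100 bp, circular shifts, ranked peaks that did not pass as background, other overlap rules, other word lengths and a summit window of 100 bp to each side. Chosen after seeing the data were an IDR of 0.001, the removal of peaks with a pooled signal under 20, the removal of peaks at small RNA genes, a wider rule for the symbols of ribosomal proteins, and the return of the absent passing peaks. All scripts ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.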

Results

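The binding of ZTF-28, a protein named as a zinc finger transcription factor, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans. The animals carried an EGFP tag, flanked by TY1 and FLAG epitopes, inserted by CRISPR at the gene's own locus on chromosome V, and chromatin was precipitated with an antibody against GFP. They were synchronised by bleaching and starvation at the first larval stage and collected as young adults at 63 hours. The design had 1 group of 2 biological replicates and no second condition, so the comparisons asked where the tagged protein was bound and how far the replicates matched. The peak lists carry no read counts, so the depth of each library is unknown, and intervals below cover counting of peaks or genes only. Positions are in assembly ce11. Signal values are the authors' own value per peak and have no replicate spread. Beside the value of the pooled libraries, the lists give 1 value for each of the 2 replicates. The first equals the signal of an overlapping peak in the ranked list of replicate 1 alone at 1077 of the 1086 reproducible peaks, and the second equals that of replicate 2 at 1080, so replicate values are given below in the order replicate 1, replicate 2. Over all 103094 ranked peaks these equalities held for 57.7% and 56.3%, and those with the opposite replicate for 0.

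Reproducible binding was found at 1086 peaks, and the largest class lay just upstream of protein-coding genes. Of the summits, 480 (44.2%, 95% Wilson interval 41.3 to 47.2) fell between 500 bp upstream and 200 bp downstream of an annotated protein-coding transcript start. Summits placed at random on the same chromosomes fell there in 16.5% ± 1.15 of cases (SD over 10000 placements; one-sided permutation p = 0.0001, the smallest they can give). Among the ranked peaks that did not pass the reproducibility threshold the share was 17.3% (two-sided Fisher exact p = 2.95e-93). Protein-coding exons outside such windows held 8.10% of summits against 23.2% of random positions, and introns held 9.12% against 27.7%. Another 160 summits (14.7%) lay outside every start window and every protein-coding gene, against 23.7% of random positions. In the protein-coding windows the median summit lay at -176.5 bp from the start, with quartiles at -273.5 and -63.75 bp, and 421 of 480 summits were upstream. Annotated starts of many worm genes are trans-splice sites, so the true start can lie further upstream.

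**Figure D1:**
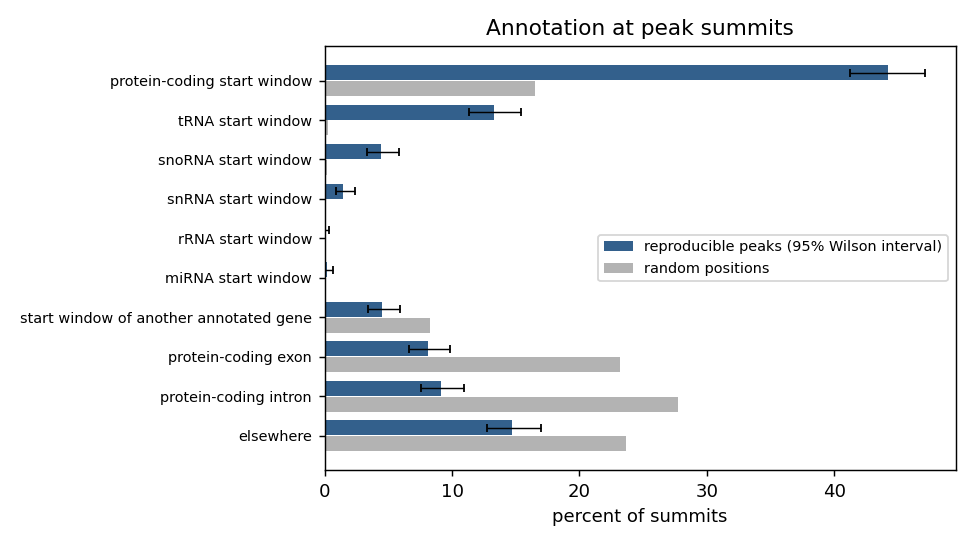
Percent of summits in each annotation class (horizontal axis) for the 1086 reproducible peaks, with 95% Wilson intervals as error bars, and for random positions. Each summit is counted in the first class that holds it, from top to bottom, and start windows of protein-coding, tRNA, snoRNA and snRNA genes hold more summits than random positions.

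Ribosomal protein genes were prominent among the strongest peaks. Of the 25 peaks with the highest pooled signal, 18 were assigned to a protein-coding gene and 5 of these genes encode cytosolic ribosomal proteins. The strongest (signal 549.8 in the pooled libraries, 290.4 and 253.2 in the replicates) lay on chromosome IV from 4727949 to 4728150, at -77 bp from the start of the pseudogene K08F11.6. A peak of signal 354.4 lay in the same stretch, from 4725522 to 4725689, at -113 bp from the non-coding RNA gene K08F11.7. The next strongest was at mog-4, which encodes a DEAH-box RNA helicase needed for the switch from sperm to oocytes (chromosome II, 14561755 to 14561977, -272 bp, signal 542.3). It was followed by K12H4.5 (chromosome III, 8043873 to 8044079, -516 bp and so just outside the window, signal 479.7) and tasp-1, a homologue of the protease taspase (chromosome III, 10759139 to 10759360, -64 bp, signal 472.2). The ribosomal protein genes were rpl-3 (chromosome III, 3867466 to 3867678, -264 bp, signal 458.5), rpl-15 (chromosome IV, signal 430.9), rps-24 (chromosome IV, signal 406.7), rpl-35 (chromosome III, signal 384.9) and rps-23 (chromosome IV, signal 337.8). Signals between 307.9 and 406.1 were found in the start windows of mtcu-2, the ubiquitin ligase gene eel-1, the Ras pathway scaffold gene cnk-1, K10D2.5, the DnaJ gene dnj-28, the mitochondrial ATPase gene atad-3, the kinetochore gene czw-1 and the non-coding RNA gene C46C2.12. The RNA component of RNase P, rpr-1, carried a peak inside the gene, at 17 bp from its start on chromosome I (13463891 to 13464042, signal 337.6), and the snoRNA genes F59C6.15 and ZK994.7 carried signals of 410.1 and 305.5. The remaining peaks lay outside every window, nearest to M04F3.7 (-581 bp, signal 414.6), Y62F5A.12 (-537 bp, 325.8), vps-39 (-501 bp, 318.6) and imb-3 (-1225 bp, 309.3).

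Peaks in protein-coding start windows had a median signal of 102.6, against 92.0 for the other peaks, a difference of 10.6 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The difference did not pass the threshold in the list of replicate 2 alone (4.05, permutation p = 0.103). It also missed it among the 301 peaks with a global irreproducible discovery rate (IDR) of at most 0.001, a threshold chosen after seeing the data (6.08, permutation p = 0.416).

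The ztf-28 gene itself (chromosome V, 2090669 to 2091740) had 0 reproducible peaks within 500 bp. Of the 4 ranked peaks there, the strongest, from 2091676 to 2091975 and overlapping the end of the gene, had a pooled signal of 51.7, replicate values of 12.9 and 37.7 and an IDR of 0.480, and stood at rank 6823 of 103094 by signal. The one with the lowest IDR, 0.278, ran from 2090407 to 2090706, across the other end of the gene, with a pooled signal of 41.0 and replicate values of 19.4 and 20.7.

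Genes for tRNAs, snoRNAs and snRNAs had the highest enrichment of the gene classes counted. tRNA start windows held 176 summits, against 3.61 ± 1.90 expected from random placement (SD, 48.8-fold; permutation p = 0.0001). The windows of snoRNA genes, whose RNAs guide the modification of other RNAs, held 65 summits against 2.75 (23.7-fold), and those of snRNA genes, which include spliceosomal RNAs, held 19 against 0.944 (20.1-fold), with the same p. Of these summits, 32 of the tRNA, 17 of the snoRNA and 3 of the snRNA class were also in protein-coding windows. By gene, 201 of 612 tRNA genes were bound (32.8%, 95% Wilson interval 29.2 to 36.7), as were 64 of 346 snoRNA genes (18.5%, 14.8 to 22.9) and 19 of 129 snRNA genes (14.7%, 9.64 to 21.9). The other annotated genes were bound in 2.103%, 2.38% and 2.47% of cases, and the adjusted p was 9.71e-166, 4.30e-35 and 3.62e-09 (two-sided Fisher exact test, Benjamini-Hochberg over 35 lists). The tRNA genes rest on 176 summits: 1 summit can lie in the windows of several clustered tRNA genes. Of the microRNA genes, 5 of 261 were bound (adjusted exact p = 0.835), whereas their windows held 6 summits against 1.87 expected from random placement (3.21-fold, unadjusted permutation p = 0.0136), and 4 of these 6 were also in protein-coding windows. Windows of the annotation class ncRNA held 208 summits against 46.4 (4.48-fold, permutation p = 0.0001), of which 62 were also in protein-coding windows. Outside the windows of protein-coding, tRNA, snoRNA, snRNA, rRNA and microRNA genes, those of all other genes held 49 summits (4.51% against 8.24% of random positions). The genes of piRNAs, the germ line small RNAs called 21U RNAs, were bound less often than other genes, at 22 of 15363 (0.143% against 3.65%, adjusted exact p = 4.91e-165). The deficit was smaller against positions than against genes: their windows held 17 summits against 45.4 from random placement (0.375-fold, permutation p = 0.0001), and the 22 bound genes compare with 115.2 ± 21.5 for shifted summits (SD, adjusted permutation p = 0.0007).

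Summits at tRNA and snRNA genes had similar positions, whereas those at snoRNA genes lay mostly upstream. In tRNA windows the median summit lay 17.5 bp downstream of the annotated start, with quartiles at -3 and 41 bp, so most lay inside the gene, and 27.3% were upstream. In snoRNA windows the median was -38 bp (quartiles -55 and -18) and 80% were upstream, whereas in snRNA windows it was 15 bp (quartiles -1 and 35.5). The strongest tRNA peaks were on X: a summit at 3036127 lay beside the glycine tRNA gene M02F4.t1 and the glutamate tRNA gene M02F4.t2 (signal 222.5), and a summit at 9743713 lay between the alanine tRNA genes F15G9.t1 and F15G9.t2 (signal 221.9). Besides the snoRNA genes named above, W03C9.9 (chromosome II, -52 bp, signal 271.6) and C51F7.3 (chromosome V, -49 bp, signal 257.1) had the highest values. The leading snRNA genes were T11F9.15 (signal 198.1), sls-2.1 (187.6), F54D8.7 (169.2) and R07E5.16 (162.9). The summit at T11F9.15 is also in the window of snr-4. Median signal was 120.1 at snoRNA genes against 94.1 at the other peaks (adjusted permutation p = 4e-05) and 113.9 at snRNA genes against 94.7 (adjusted permutation p = 0.0364). tRNA peaks were not distinguishable from the rest, at 96.0 against 94.6 (adjusted permutation p = 0.583, 4 lists compared). The comparisons of signal in these 4 lists, of which cytosolic ribosomal protein genes are the last, were not in the plan.

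**Figure D2:**
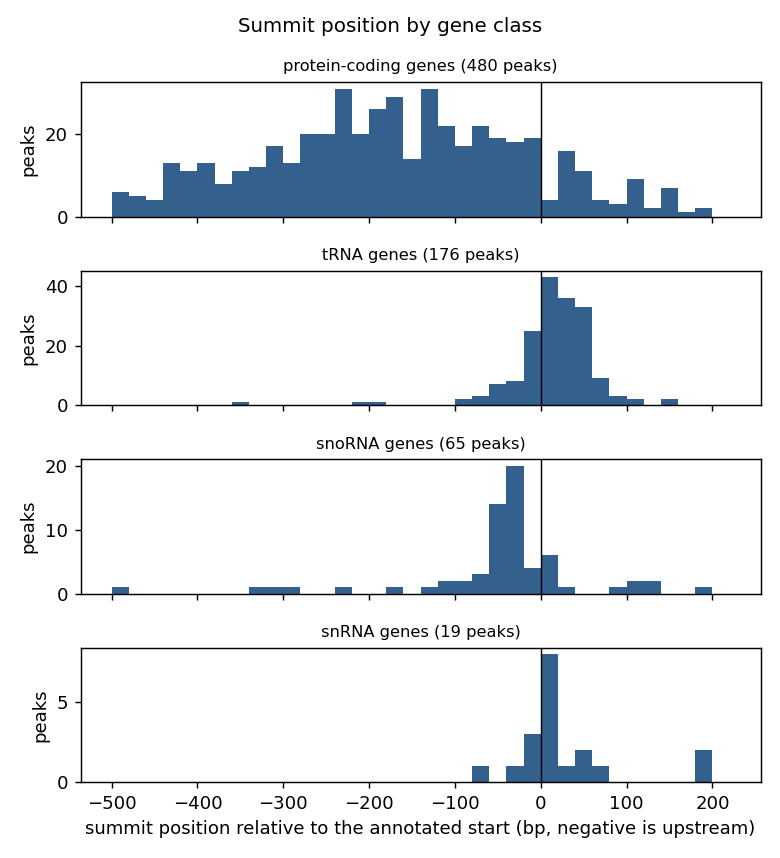
Number of peaks (vertical axes) by summit position in bp from the nearest annotated start whose window holds it, in bins of 20 bp, for protein-coding, tRNA, snoRNA and snRNA genes. Summits spread over the upstream side of protein-coding starts, gather inside tRNA genes (median 17.5 bp) and gather just upstream of snoRNA genes (median -38 bp).

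Among protein-coding genes, those of the cytosolic ribosome stood out. Summits lay in the windows of 23 of 76 cytosolic ribosomal protein genes (30.3%, 95% Wilson interval 21.1 to 41.3), against 2.89% of other protein-coding genes (adjusted exact p = 2.01e-16). In a comparison outside the plan, the peaks were stronger than the rest (median signal 143.9 against 94.6, adjusted permutation p = 4e-05). These genes rest on 22 summits, of which 3 were also in snoRNA windows, and without peaks at small RNA genes 20 of 76 were bound (adjusted exact p = 2.14e-13). The list was made from symbols ending in a number, which left out the bound gene rpl-7A (signal 224.2). The same summit is also in the window of the snoRNA gene Y24D9A.9. With symbols ending in a letter and the rla genes added, 24 of 81 were bound (adjusted exact p = 6.99e-17), a count that keeps peaks at small RNA genes. Mitochondrial ribosomal protein genes had 0 of 66 bound, which allows a share of up to 4.55%, and did not pass (adjusted exact p = 0.410). Translation factors were bound at 6 of 31 genes (adjusted exact p = 0.00101), with the highest signals at eif-3.E (150.9), eef-1A.1 (109.0), eef-2 (107.0) and eef-1A.2 (91.8). Splicing factors were bound at 6 of 33 (adjusted exact p = 0.00124), led by the Sm protein genes snr-4 (198.1) and snr-1 (167.5), while rsp-1 and rsp-2 share 1 summit (93.5). Respiratory chain genes were bound at 6 of 39 (adjusted exact p = 0.00288), among them cox-5B (233.5), atp-5 (151.1), cox-6B (133.7) and atp-1 (118.5). Heat shock protein genes were bound at 4 of 23 (adjusted exact p = 0.0112), namely hsp-90 (192.0), hsp-1 (171.6), hsp-110 (109.2) and hsp-3 (103.9). Histone genes were bound at 9 of 72 (adjusted exact p = 0.00101), but these rest on 5 summits, of which 4 are shared by pairs of genes, such as his-67 and his-68 (241.7) and his-61 and his-62 (119.6). How far reads were shared between similar histone genes was not tested. No control library was analysed. A general affinity of open or highly transcribed chromatin for the immunoprecipitation was therefore not tested for any of the lists.

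The list of oocyte and germ granule genes and that of DNA replication and cell cycle genes were also bound more often than other protein-coding genes, while other germ line lists did not pass. Of the oocyte and germ granule list, 8 of 35 genes were bound (22.9%, 12.1 to 39.0, adjusted exact p = 3.55e-05), with cpg-1, an eggshell proteoglycan gene, at a signal of 282.5, the maternal RNA-binding protein gene pos-1 at 140.1, the poly(A) polymerase gene gld-2 at 107.4 and the egg surface gene egg-1 at 99.6. Of the DNA replication and cell cycle list, 8 of 37 were bound (21.6%, 11.4 to 37.2, adjusted exact p = 4.83e-05), led by the retinoblastoma homologue lin-35 (167.8), mcm-2 (156.6), pcn-1 (155.1) and pola-1 (105.2). Meiosis genes had 3 of 29 bound (adjusted exact p = 0.113) and Argonaute and small RNA factors 3 of 41 (adjusted exact p = 0.228). Sperm protein families had 0 of 57 bound, which allows up to 5.26%.

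No list of somatic tissue markers passed the threshold in either direction. Of the intestine list only asp-1, an aspartic protease gene, was bound (1 of 15, 6.67%, signal 87.5, adjusted exact p = 0.534). The lists for body muscle (0 of 14), pharynx (0 of 11), neurons (0 of 18) and hypodermis (0 of 15) had no bound member, and each adjusted p was 1. Counts of 0 in these lists allow shares of up to 21.4%, 27.3%, 16.7% and 20%, so they are too short to show a difference from the 3.00% found in other genes. Families with no call and a bound share below that of other protein-coding genes were the ztf genes (0 of 25, allowing up to 12%), vitellogenins (0 of 6, allowing up to 50%), collagens (1 of 156, 0.641%), homeobox genes (1 of 87, 1.15%), nuclear hormone receptors (4 of 269, 1.49%), neuropeptides and insulins (1 of 140, 0.714%) and detoxification enzymes (1 of 185, 0.541%). Also without a call, but with a share above that of other genes, were aminoacyl-tRNA synthetases (1 of 32, 3.13%), the vacuolar ATPase (1 of 20, 5%) and the proteasome (2 of 33, 6.06%). The bound vacuolar ATPase gene has the same signal value as pos-1, and 1 of the 2 bound proteasome genes the same as hsp-110. Each of these pairs may rest on 1 shared summit. Chemoreceptor genes were bound less often than other protein-coding genes (5 of 1364, 0.367% against 3.19%, adjusted exact p = 5.09e-12), with srh-269 the strongest (119.4), then srh-36 (98.3), sri-5 (90.4) and srh-170 (83.0). The same held for F-box genes (1 of 322, fbxa-15 at 83.0, adjusted exact p = 0.00357) and C-type lectins (1 of 240, clec-126 at 98.7, adjusted exact p = 0.0269). The chemoreceptor, F-box and C-type lectin lists did not pass against summits shifted along the chromosomes, where the log2 ratio was -0.87, -1.09 and -0.67 instead of log2 odds ratios of -3.03, -2.75 and -2.32. In all, the Fisher exact tests called 11 of the 35 lists as bound more often and 4, these 3 and piRNA genes, as bound less often. The same tests called a list in 20 of 100 random sets, so calls near the threshold are uncertain.

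The calls for tRNA, snoRNA, snRNA, piRNA and cytosolic ribosomal protein genes stayed past the threshold under each alternative run, and others did not. The ribosomal protein list weakened with the start window of 250 bp upstream and 100 bp downstream, from 23 to 6 bound genes (log2 odds ratio from 3.88 to 2.32, adjusted exact p = 0.0107). For tRNA genes the log2 odds ratio fell from 4.51 to 3.72 with the list of replicate 2 alone, 3.42 with that of replicate 1 alone and 3.34 at an IDR of 0.001, where 70, 49 and 45 genes were bound, whereas for snoRNA genes it rose from 3.22 to 3.75, 3.90 and 3.77. The higher rank of tRNA genes therefore holds for the list from both replicates and not for these shorter lists. Against summits shifted together along each chromosome, chemoreceptors (5 bound against 9.52 ± 3.10, SD, adjusted permutation p = 0.359), F-box genes (1 against 2.69 ± 1.75, 0.898) and C-type lectins (1 against 1.89 ± 1.39, 1) lay below the shifted mean without passing the threshold, while meiosis genes passed (0.0199), as they did with the optimal list (adjusted exact p = 0.0245). With the list of replicate 2 alone the calls ended for histones (adjusted exact p = 0.0581), translation factors (0.634), splicing factors (0.184), oocyte genes (0.634), C-type lectins (0.193) and F-box genes (0.0787). With that of replicate 1 alone they ended for replication genes (adjusted exact p = 0.186), heat shock proteins (0.0929), splicing factors (0.511), C-type lectins (0.284) and F-box genes (0.169). The narrower start window ended the calls for translation factors (adjusted exact p = 0.0551), splicing factors (0.240), respiratory chain genes (0.0930), heat shock proteins (0.154) and C-type lectins (0.257), and with a window of 1000 bp upstream C-type lectins missed the threshold at 0.0572 while Argonaute and small RNA factors passed at 0.0471. At an IDR of 0.001 the calls ended for histones (adjusted exact p = 0.423), translation factors (0.538), splicing factors (0.162), heat shock proteins (0.109), oocyte genes (0.162), C-type lectins (0.281) and F-box genes (0.162). Not every lost call was a much smaller difference, since the shorter lists and the narrower window also leave fewer bound genes. With the narrower window the log2 odds ratio went from 3.06 to 2.72 for translation factors, from 2.66 to 2.36 for respiratory chain genes, from 2.91 to 2.64 for heat shock proteins and from 2.95 to 2.09 for splicing factors. At an IDR of 0.001 it was 3.34 for heat shock proteins, 2.70 for oocyte genes and 1.62 for histones, with 2 bound genes each. With replicate 2 alone it went from 2.29 to 2.27 for histones (4 bound genes). With replicate 1 alone it went from 2.91 to 3.31 for heat shock proteins (2 bound genes). It dropped with replicate 2 alone for oocyte genes, from 3.34 to 1.66, and for translation factors, from 3.06 to 1.84. F-box genes and C-type lectins had 0 bound genes in each single-replicate list and at an IDR of 0.001. A small constant was added to each count, and with 0 bound genes it sets the log2 odds ratio. Whether these 2 deficits changed there cannot be told.

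**Figure D3:**
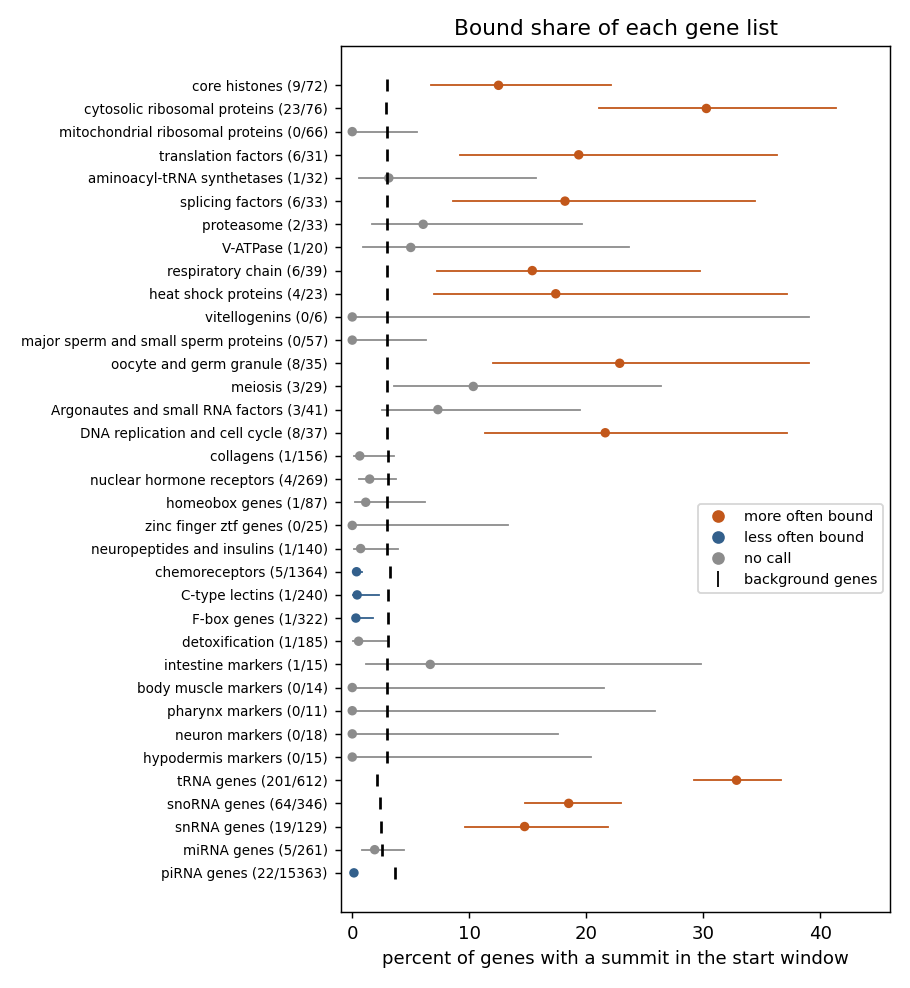
Percent of the genes in each list with a summit in their start window (points) with 95% Wilson intervals (lines), and the percent of the background genes (black ticks); bound and total genes are given beside each name. tRNA genes (32.8%) and cytosolic ribosomal protein genes (30.3%) have the highest shares.

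Fewer peaks lay on the X chromosome than its length would give. X held 107 of 1086 peaks (9.85%) against 17.7% of the nuclear genome, a ratio of 0.558 (exact 95% interval 0.461 to 0.667; two-sided exact binomial p = 5.91e-13, adjusted p = 3.55e-12 over 6 chromosomes). Of the X peaks, 64 lay in tRNA windows outside protein-coding ones and 19 in protein-coding windows. The ratio was 1.36 on chromosome III, 1.30 on I, 1.19 on II, 1.01 on IV and 0.772 on V, with adjusted p of 1.62e-05, 8.87e-05, 0.0106, 0.905 and 0.000129. The share on X was 7.602% in the list of replicate 1 and 11.4% in that of replicate 2 (two-sided Fisher exact p = 0.0839).

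The DNA at the summits was rich in G and C. Within 50 bp of the summit the mean GC content was 49.0%, against 36.2% in flanks 300 bp away, a difference of 12.8 percentage points ± 10.4 (SD over 1086 peaks) that was positive at 88.7% of peaks (two-sided sign-flip permutation p = 1e-05). The difference was 15.4 points at the 176 tRNA peaks and 11.2 at 424 protein-coding start peaks without a small RNA gene. The best word of 8 bases, chosen in the peaks of odd rank, was CTGAGCTA. In the peaks of even rank it occurred at 19 of 543 summits (3.50%) and in the flanks of 0.184% (two-sided exact sign test p = 4.01e-05). All of these 19 summits lay in tRNA windows, where 22.4% of even-ranked peaks had it, against 0 of 458 elsewhere, which allows a share of up to 0.655%. Of 612 tRNA genes, 472 have identical copies, so peaks of odd and even rank can hold the same sequence. The test is then not independent of the choice. It does not tell a bound word apart from the enrichment at tRNA genes. With the list of replicate 1 alone the best word was GGAGCAGA, which did not pass (2.34%, exact p = 0.375). With words of 6 bases the best was CGCGGC, at 10.9% of even-ranked summits and in the flanks of 0.921% (exact sign test p = 9.00e-13). Another leading word of 8 bases, GCGCGAAA, occurred at 17 even-ranked summits (3.13%) and in the flanks of 0% (exact sign test p = 1.53e-05). How many of these summits lay in tRNA windows was not counted.

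The replicates shared most peaks of the shorter single-replicate list. The list of replicate 1 alone held 342 peaks and that of replicate 2 alone 411. Of the shorter list, 219 peaks (64.04%, 58.8 to 68.9) overlapped a peak of the other by at least 1 bp, against 0.232% ± 0.259 for random placements (SD; one-sided permutation p = 0.0001). Across the 1131 ranked peaks that passed, the replicate values had a Pearson r of 0.72 on the log2 scale and a Spearman rho of 0.45 (both permutation p = 1e-05). This correlation is across peaks, which are not independent replicates, and over peaks selected for agreement of ranks. Over all 103094 ranked peaks r was 0.26 and rho 0.27 (both permutation p = 0.0001). The conservative and pooled lists, of 1086 and 1137 peaks, gave a rescue ratio of 1.05, and the single-replicate lists a self-consistency ratio of 1.20. The conservative list was 2.64 times as long as the longer single-replicate list.

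**Figure D4:**
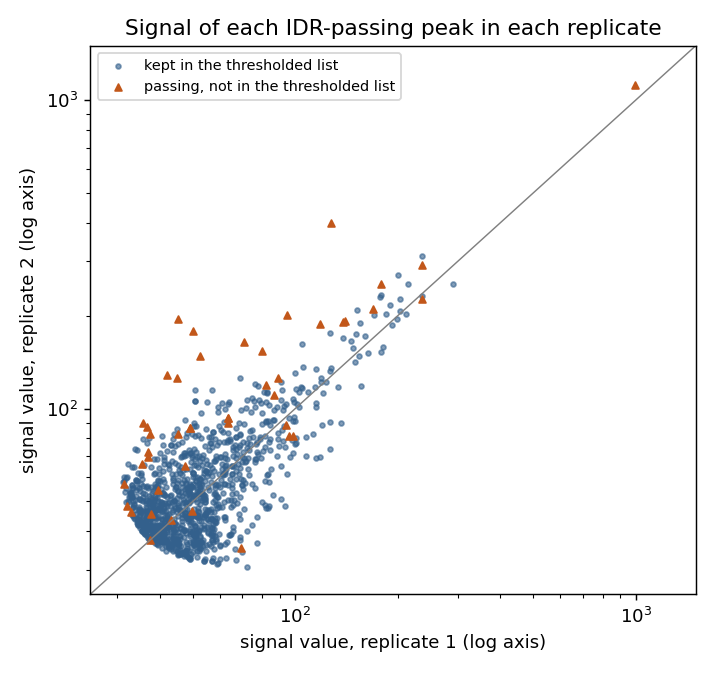
Signal value of each of the 1131 passing peaks in replicate 1 (horizontal) and replicate 2 (vertical; both log axes, authors' units); the line marks equal values. Triangles are the 45 passing peaks absent from the thresholded list, and the strongest of them lies at the top right, far from the other points.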

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

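A group of 45 peaks passed the authors' IDR threshold in the ranked list but is absent from the thresholded list, so it lies outside the comparisons above, apart from the correlation of replicate values and its figure. It includes the strongest peak in the ranked list, with a pooled signal of 1977.0 and replicate values of 996.3 and 1121.1. That peak lies on X from 15810995 to 15811145, outside any annotated gene, and the nearest start, of the pseudogene Y7A5A.11, puts its summit at -856 bp. No control library was analysed, and the value was set against the strongest peak of the thresholded list, which has a signal of 549.8. The absent peaks had a median signal of 149.8 against 94.8 for the peaks kept. Only 6 of the 45 overlapped an annotated gene and 0 had their summit in a protein-coding start window, which allows up to 6.67%, against 44.2% of the peaks kept (two-sided Fisher exact p = 1.22e-11). Several of them form clusters, for example 10946019 to 10949652 on chromosome I and 7446423 to 7448138 on chromosome III. The value of replicate 2 was the higher in 38 of the 45, and in 57.4% of the peaks kept. Why these peaks were left out was not tested, and no biological explanation was tested.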

How the results depend on the processing

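Across the alternatives, 76 values of the main results kept their direction and their side of the threshold, or stayed within 1.5 times for counts, and 8 did not. The promoter share ranged from 29.5% to 55.1%, the X ratio from 0.430 to 0.647, the GC difference from 9.23 to 14.5 points and the replicate overlap from 59.1% to 64.7%, all past the threshold. An IDR of 0.001, chosen after seeing the data, left 301 peaks, 8 lists past the threshold and a promoter signal difference of 6.08, which did not pass (fewer peaks were tested). Leaving out each replicate in turn gave peak counts of 342 to 411, signal differences of 4.05 to 5.28, best word shares of 2.34% to 4.39% with other words, and 9 to 10 lists. Here the lists come from 1 library alone, and the cause of the losses was not tested. For the gene lists called under any setting, 27 values no longer passed and 3 newly passed, with no change of direction. The stricter IDR of 0.01 removed no peak of the thresholded list and only 2 of the 1131 in the signal correlation, so it says nothing about stability. Its values are nevertheless counted among the 76. Unknown depth limits what the absence of a peak shows.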

Other observations

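Of the tests below, those of equal size on X, of overlap with a stronger peak, of equal offsets from drawn starts and of the best word away from small RNA genes were chosen after the result was seen, and those by amino acid and of snoRNA genes on X were not in the plan. Binding at tRNA genes was spread over amino acids: 21 of the 22 classes, counting tRNA genes without a named amino acid as a class, had a bound gene, with shares from 14.3% for phenylalanine (2 of 14) to 46.2% for cysteine (6 of 13), and the single selenocysteine gene was not bound. None of the classes differed from the others after adjustment (lowest adjusted two-sided Fisher exact p = 0.926). Of the sls-2 genes, which encode trans-spliced leader RNAs, 5 of 18 were bound (27.8%, 95% Wilson interval 12.5 to 50.9), a family picked after its values were seen. Away from small RNA genes, the best word was GCGAGACC, at 3.90% of even-ranked summits against 0.488% of flanks (exact sign test p = 0.000275).

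About the tRNA peaks, 3 technical explanations were tested. Reads shared between identical copies would leave single-copy genes unbound. Of the tRNA genes whose sequence occurs only once in the genome, 24.3% were bound (34 of 140, 17.9 to 32.01). The share was higher, at 35.4%, for genes with identical copies (167 of 472, two-sided Fisher exact p = 0.0141). With 100 bp to each side included, 610 of 612 genes are unique, so it decides nothing that all 201 bound genes were among them. Near-identical copies and summits shared with a neighbouring tRNA gene were not set apart. Shared reads may add to the count of bound genes, and how far they account for the peaks cannot be told. A bias for tRNA sequence could also mark tRNA pseudogenes, of which 2.87% were bound (6 of 209, Fisher exact p = 1.27e-22 against tRNA genes). How far the sequences of pseudogenes differ from those of tRNA genes was not measured, so this cannot decide on such a bias. Neighbouring protein-coding starts do not account for the binding at tRNA genes, since 31.3% of those with no such start within 1000 bp were bound (121 of 386). A general affinity of open or highly transcribed chromatin for the immunoprecipitation stays open, as no control library was analysed, and no biological explanation was tested.

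The deficit on X was a feature of protein-coding genes more than of tRNA genes. Peaks that did not pass had an X ratio of 0.867, against 0.558 for those that passed (Fisher exact p = 2.06e-07), so the deficit was larger among passing peaks. Lower coverage of X need not lower both kinds of peak alike, and depth is unknown. How far coverage accounts for the deficit therefore cannot be told from these values. Fewer genes on X are not enough, since 0.696% of protein-coding genes on X were bound (19 of 2731) against 3.36% on autosomes (579 of 17242, Fisher exact p = 1.24e-18), as were 0 of 33 snoRNA genes (allowing up to 9.09%) against 64 of 313 (p = 0.00148). tRNA genes were bound at 31.9% on X (88 of 276) and 33.6% on autosomes (113 of 336, p = 0.666), which cannot be told apart from a small deficit. The difference of log2 odds between tRNA and protein-coding genes, 2.16 (95% interval 1.34 to 2.98), argues against a deficit of equal size in both. The interval counts genes as independent, although neighbouring tRNA genes can share a summit, so it may be too narrow. No biological explanation was tested, since the design has 1 group.

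Some 25 peaks passed although their pooled signal was only 2.31 to 17.7, while their replicate values lay between 32.1 and 106.1. A candidate explanation is that each lies beside a stronger pooled peak and was matched with the same replicate peaks: all 25 overlapped a stronger ranked peak, and all 25 a stronger peak of the thresholded list. These may be second entries for the same sites, and merging overlapping peaks leaves 1051 regions.

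A hypothesis written before its test was that peaks at protein-coding starts favour stretches between genes on opposite strands. Of the 480 such peaks, 132 (27.5%) lay in start windows of genes on both strands, against 5.94% ± 1.07 for positions drawn at random inside the windows (SD; one-sided permutation p = 0.0001). Summits lie mostly upstream of starts, where such overlaps are more common. With the same offsets from starts drawn at random on the same chromosomes the share was 12.2% ± 1.504 (SD; permutation p = 0.0001), so the offsets account for only part of the excess. Both results are consistent with the hypothesis, found and tested on the same peaks.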
